A study of Homo sapiens with 6 samples.

How the data were processed

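Total RNA was taken from cells labelled HepG2, 48 h after transfection with a negative control siRNA or an siRNA against RNF43, and 6 µg per sample went into biotin-labelled cRNA hybridised to HG-U133 Plus 2.0 arrays, per the labels' protocols. The sense strands were CAGAACAGAAAGCUAUUAUTT for RNF43 and UUCUCCGAACGUGUCACGUTT for the control, per the labels. Where these lie in transcripts was not analysed here. The deposited values are log2 signals, and the submitters' processing notes name MAS5, the Affymetrix algorithm that sets perfect-match against mismatch probes and scales each array. Its version and scaling target are not given in the sources used here. The log base was read from the values. Taken as base 2, the linear means trimmed by 2% at each end agreed across arrays at 497.03 to 497.23, so the arrays had already been scaled. MAS5 subtracts a mismatch signal, which makes dim probe sets noisy, and 391 to 628 values per array sat at exactly 0, read as a floor. No tested gene had a value at this floor. Scaling to a common mean would hide a shift of all transcripts in one direction. Detection calls, scan dates and scanner batches were not used here.

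Each array was assigned to its group and replicate by its title, giving 3 arrays per group. No 2 arrays held identical values, with at most 0.00183% of values above the floor equal within a group. Values were used as given, with no further normalization. Gene names came from the platform annotation, updated to RefSeq symbols of the GRCh38.p14 table, which served for names and gene order only. Of the 54613 probe sets, 41091 named 1 gene, 1801 named several and 11721 were unnamed here. Genes were taken from probe sets naming 1 gene, 19775 genes in all, by the probe set with the highest mean log2 signal over the 6 arrays. A gene was tested if that mean lay in the upper 50% of probe sets (log2 above 5.83), which left 11853 genes. RNF43 was always to be tested.

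Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values are means ± SD over 3 arrays per group, and SE refers to the log2 difference. For RNF43 alone an exact permutation test of 3 against 3 arrays was added, whose smallest p is 0.1. Gene lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of 1029 genes in 38 lists, 923 were matched and 753 tested. A list symbol was matched as written, or through a unique synonym if it is no gene's current symbol. That last condition was added after the results were seen, and took 4 wrong matches out of 3 lists that had not changed. The lists, the gene and list tests and all but 1 of the alternatives were fixed before the data were examined. Named genes followed a rule fixed then too. It takes RNF43, the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap, and up to 4 members with the smallest p in each described list. Outside that rule, PRIM1 and PMVK, which moved against their lists, the plasma protein genes ALB, APOA1, TTR, FGB and SERPINA1, and the histone genes of the closing observations were chosen after their values were seen.

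The steps were tested on simulated data with the real arrays' means and spread. Over 11882 simulated genes compared as RNF43 siRNA against control siRNA, 39.4% of genes changed by 0.5 on the log2 scale were called, 90.8% of those changed by 1 and 98.4% of those changed by 2. Of all calls, 3.97% were on unchanged genes. The simulation changed 200 genes and shifted 1 list, a smaller share than the 22.6% called in the real comparison. Its noise was drawn independently for each probe set, with no effect shared by arrays. These shares therefore do not give the power or the false calls of the real comparison. The alternatives covered normalization, added signal, filters, variance models, array weights, the choice of probe sets, a replicate block, thresholds, set tests and leaving out each array. Because the values were already on a log2 scale, they were used as given and the planned pseudocount of 16 was not used. In place of other pseudocounts, 1 or 64 was added to the linear signal. The planned comparison of 3' and 5' control probe sets was not run, since no control probe sets were used here. One added alternative, both arrays numbered 3 left out, was chosen after the data were seen. Of the explanations weighed in the closing section, 2 further tests were run and then left out. Removing the 2 cell cycle lists from the count of changed genes could not decide anything, since the lists are too small to move it, and histone probe sets ending in _at alone, run as a test of binding to related transcripts, are given as values only. The test of other splits was first marked as written before its result was seen, and was corrected to after.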

Results

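Messenger RNA levels were measured on 6 Affymetrix arrays of cells labelled HepG2, a human line derived from a liver tumour. The cells had been transfected with a negative control siRNA on 3 arrays and with an siRNA against RNF43 on the other 3, and RNA was taken 48 h later. RNF43 is a membrane ubiquitin ligase that removes Frizzled receptors from the cell surface and so restrains Wnt signalling. The labels call the 3 arrays of each group biological replicates. They do not say whether these came from separate cultures, so p-values measure the spread between these arrays, part of which may be technical. The arrays held 54613 probe sets each, with median log2 signals of 5.89 to 6.02, and their number limits the precision. Across the 11853 genes tested, Pearson's r between arrays of one group was 0.987 to 0.991, and between arrays of different groups 0.975 to 0.980. These correlations run across genes, which are not independent replicates.

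The comparison asked how transcript levels differed 48 h after transfection with the RNF43 siRNA. RNF43 itself, read by its single probe set, went against its label. Its log2 signal was 7.63 ± 0.17 (SD, n = 3) on the control arrays and 8.27 ± 0.12 (SD, n = 3) on the arrays labelled RNF43 siRNA. This made RNF43 1.56-fold higher where the siRNA against it was named, with a 95% confidence interval of 1.25 to 1.95 and a log2 difference of 0.64 (SE 0.14, limma adjusted p = 0.0098). All 3 control values lay below all 3 others, and the exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 arrays allow. With both arrays numbered 3 left out, an alternative chosen after the data were seen, the difference was 0.48 and no longer passed the threshold (adjusted p = 0.0537, range over all alternatives 0.00585 to 0.0537). Every direction given here is that of the arrays labelled RNF43 siRNA relative to the control arrays, and is not tied to a measured loss of RNF43 mRNA.

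**Figure D1:**
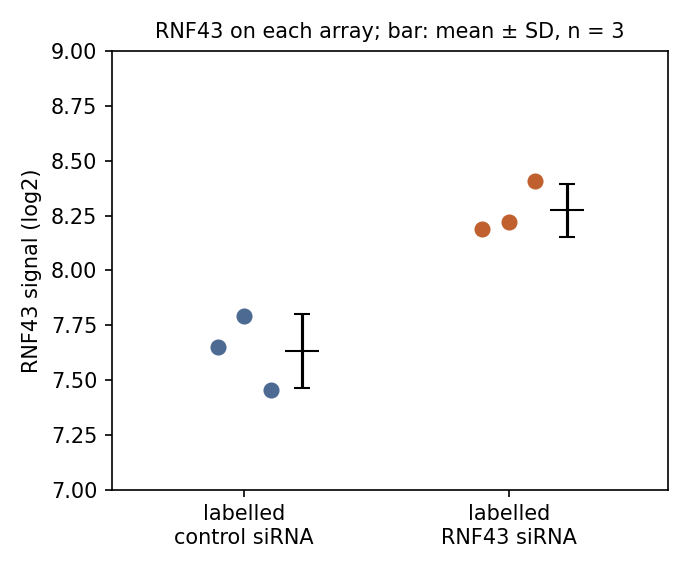
Log2 signal of RNF43 on each array (points), with the mean ± SD of each group of 3 arrays beside them; the signal axis does not start at 0. The control arrays lay between 7.45 and 7.79, and the arrays labelled RNF43 siRNA between 8.19 and 8.41.

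Many transcripts differed between the groups. In limma's camera test with a preset correlation between genes, lists of DNA replication, mitosis, YAP/TAZ signalling and cholesterol synthesis genes were higher on the arrays labelled RNF43 siRNA, and lists of endoplasmic reticulum protein folding, interferon response, proteasome and amino acid stress response genes and of fibroblast and stellate cell markers were lower. With an estimated correlation 0 of these lists passed, and in each of them 4 to 21 tested members did not change. Of the 11853 genes tested, 2684 (22.6%) changed, 1364 of them higher and 1320 lower (limma, adjusted p under 0.05). Most changes were small, with a median of 1.39-fold among risen genes and 1.39-fold among fallen genes. At least 2-fold changes were seen for 114 risen and 90 fallen genes. The values of the groups did not overlap for 38.9% of tested genes, against 10% by chance. Leaving out RNF43 siRNA replicate 2 lowered the count to 1741 genes.

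Among the largest rises were 6 genes with adjusted p from 1.995e-06 to 3.23e-04 and mean log2 signals of at least 7.58. GNB4, a G protein beta subunit, was 4.15-fold higher on its brightest probe set (log2 difference 2.05, SE 0.11). The 1 other tested GNB4 probe set did not change, and the mean of its probe sets gave a log2 difference of 0.97. NCEH1, a cholesteryl ester hydrolase, rose 4.10-fold and ADAM9, a membrane metalloprotease, 4.05-fold on its brightest probe set. Of 2 other tested ADAM9 probe sets, 1 also rose, and the mean gave a log2 difference of 1.06. HTRA1, a secreted serine protease, rose from 8.55 ± 0.05 to 10.57 ± 0.14 (SD, n = 3), or 4.05-fold. ASPH, a hydroxylase of aspartate and asparagine residues, rose 3.77-fold on its brightest probe set. Of 5 other tested ASPH probe sets, 1 also rose and 1 fell, and the mean gave a log2 difference of 0.59. RARRES2, the gene of the chemokine-like protein chemerin, rose 3.71-fold.

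The other 6 largest rises were of genes with mean log2 signals of 5.84 to 6.83. The control means of EDN2, CCDC106, PLA2G3, HES5 and FAM81A lay below the filter of 5.83, so their folds and ranks rest on a side not shown to be above background and are not exact. EDN2, which encodes endothelin 2, was 6.36-fold higher with a control SD of 1.5 log2 units, and its log2 difference of 2.67 became 1.99 without control siRNA replicate 1 and 3.47 without control siRNA replicate 2. CCDC106 was 4.71-fold higher (control SD 1.71), DNMT3L, a cofactor of DNA methyltransferases, 3.72-fold (control SD 1.32), and PLA2G3, a secreted phospholipase, 3.56-fold (control SD 1.10). HES5, a Notch target gene, rose 3.54-fold and FAM81A 3.50-fold. With 64 added to the linear signal, the log2 differences were 1.33 for EDN2, 0.91 for CCDC106, 1.11 for DNMT3L, 1.0 for PLA2G3, 0.88 for HES5 and 0.82 for FAM81A.

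H2BC5, a histone H2B gene, showed the largest fall, from 12.86 ± 0.09 to 10.59 ± 0.18 (SD, n = 3), which was 4.83-fold (SE of the log2 difference 0.09, adjusted p = 1.928e-06). Its probe set ends in _x_at, a mark of probes that can bind related transcripts. The zinc finger gene ZNF616 fell 3.68-fold and the related ZNF702P, a pseudogene, 3.55-fold. GRIK2, a kainate receptor subunit, fell 3.59-fold and SPP1, which encodes osteopontin, 3.53-fold. FAM133A was 3.48-fold lower, POLR2J2, an RNA polymerase II subunit gene with near-identical copies, 3.39-fold, and POU2F2, a transcription factor of B cells, 3.35-fold. A pair of endoplasmic reticulum genes fell with small errors. FKBP14, a collagen-folding prolyl isomerase, was 3.28-fold lower (SE of the log2 difference 0.08) and GANAB, a glucosidase that trims N-glycans, 3.18-fold lower (SE 0.11). SPRR3, a cornified envelope gene, fell 3.15-fold and ALDH1L2, a mitochondrial folate enzyme, 3.11-fold. The means of GRIK2, ZNF702P, POLR2J2, POU2F2 and SPRR3 on the arrays labelled RNF43 siRNA also lay below the filter, with the same limit on their folds and ranks. With 64 added to the linear signal, the log2 differences were -1.10 for GRIK2, -0.88 for ZNF702P, -0.83 for POLR2J2, -0.81 for POU2F2, -0.97 for SPRR3 and -0.99 for ALDH1L2. The call of CCDC106 was lost in both fits without 1 array in which it passed the filter, those without control siRNA replicate 1 or 3, and in 7 of the 12 alternatives that tested it (adjusted p 0.00528 to 0.135 over all alternatives). Without an intensity trend in the fit, the calls of DNMT3L, PLA2G3 and POU2F2 were lost, and with no filter on low values that of POU2F2. The call of DNMT3L was also lost without control siRNA replicate 2 or any 1 array labelled RNF43 siRNA (8.43e-04 to 0.0873), and its log2 difference of 1.89 lay between 1.19 and 2.51 without 1 array. PLA2G3 was also lost without RNF43 siRNA replicate 2 or 3 (0.00332 to 0.0575), with a log2 difference of 1.83 that became 1.21 without control siRNA replicate 3. POU2F2 was also lost without any 1 control array or RNF43 siRNA replicate 1 (0.00518 to 0.146), with a log2 difference of -1.74 that became -0.88 without that last array.

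Of 38 gene lists fixed before the data were examined, 37 could be tested, and 9 changed in limma's camera test, 4 higher and 5 lower on the arrays labelled RNF43 siRNA. With an estimated correlation between genes 0 of the 37 passed in camera, and 5 had an unadjusted p under 0.05, while 17 passed in limma's fry test. The adjusted p with an estimated correlation is given beside each.

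DNA replication and G1/S genes were higher. Of 34 tested members, 18 rose and 1 fell, or 24 and 1 adjusted over the list alone, with a median of 1.25-fold higher (camera adjusted p = 8.17e-08, adjusted p = 0.261 with an estimated correlation). CCNE2 and CDK2, cyclin E2 and its kinase, rose 2.67-fold and 2.65-fold. SLBP, which binds histone mRNA in S phase, rose 2.16-fold, and MCM7 of the replicative helicase 1.49-fold. PRIM1, a primase subunit named after its value was seen, was the member that fell, by 1.45-fold.

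Mitosis and G2/M genes were also higher, with 15 of 36 tested members risen and 0 fallen, and 18 and 0 adjusted over the list alone (median 1.18-fold, camera adjusted p = 2.17e-05, adjusted p = 0.554 with an estimated correlation). TOP2A, a topoisomerase, rose 1.47-fold and FOXM1, a transcription factor of the G2/M program, 1.45-fold. The mitotic kinase gene AURKA rose 1.36-fold and the spindle gene NUSAP1 1.31-fold on their brightest probe sets. Both calls were lost with the mean of a gene's probe sets, at adjusted p = 0.286 for AURKA, which was also lost without probe sets ending in _x_at and _s_at (0.8, range over all alternatives 3.08e-05 to 0.8), and 0.607 for NUSAP1 (1.92e-04 to 0.607). For TOP2A that mean lowered the log2 difference from 0.55 to 0.36.

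Target genes of the Hippo pathway effectors YAP and TAZ were higher. Of 22 tested members, 10 rose and 0 fell, or 11 and 0 adjusted over the list alone (median 1.24-fold, camera adjusted p = 1.04e-04, adjusted p = 0.279 with an estimated correlation). The receptor tyrosine kinase AXL rose 1.63-fold, AJUBA 1.48-fold, and AMOTL2, an inhibitor of YAP, 1.43-fold. TEAD1, the DNA-binding partner of YAP, rose 1.46-fold on its brightest probe set, a call that was lost with the mean of its probe sets (adjusted p = 0.781, range over all alternatives 3.27e-06 to 0.781).

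Cholesterol synthesis genes rose in 10 of 18 tested members and fell in 1, or 11 and 1 adjusted over the list alone. The median was 1.28-fold higher (camera adjusted p = 1.07e-04, adjusted p = 0.173 with an estimated correlation), or 0.36 on the log2 scale for the cholesterol synthesis list, and 0.22 without probe sets ending in _x_at and _s_at. TM7SF2, a sterol reductase, rose 2.43-fold (log2 difference 1.28, and 0.78 with 64 added to the linear signal) and MSMO1, a methylsterol oxidase, 1.71-fold. SC5D, a desaturase, rose 1.5-fold and ACAT2 1.37-fold. PMVK, the phosphomevalonate kinase, also named after its value was seen, fell 1.76-fold.

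Endoplasmic reticulum chaperones and genes of the unfolded protein response were lower on the arrays labelled RNF43 siRNA. Of 26 tested members, 11 fell and 1 rose, or 14 and 1 adjusted over the list alone, with a median of 1.22-fold lower (camera adjusted p = 1.07e-04, adjusted p = 0.173 with an estimated correlation). PDIA4, a protein disulfide isomerase, and DNAJC3, a co-chaperone that inhibits PERK, each fell 1.40-fold, and CRELD2 fell 1.31-fold. DNAJB9, a co-chaperone of BiP, was the member that rose, 1.54-fold.

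ATF4 and amino acid response genes were lower as well, with 11 of 27 tested members fallen and 1 risen, and 12 and 2 adjusted over the list alone (median 1.18-fold lower, camera adjusted p = 0.00932, adjusted p = 0.554 with an estimated correlation). The median log2 difference of the ATF4 and amino acid response list was -0.24, and -0.13 without control siRNA replicate 2. DDIT3, the stress transcription factor CHOP, fell 1.71-fold, and the pseudokinase gene TRIB3 1.49-fold. EPRS1, an aminoacyl-tRNA synthetase, fell 1.45-fold (log2 difference -0.54, and -0.98 with the mean of its probe sets) and SLC7A11, the cystine transporter, 1.42-fold.

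Interferon-stimulated genes fell in 11 of 33 tested members and rose in 2, with the same counts adjusted over the list alone (median 1.13-fold lower, camera adjusted p = 0.00318, adjusted p = 0.554 with an estimated correlation). The list also did not pass in fry (adjusted p = 0.0578, range over all alternatives 1.19e-04 to 0.554). The median log2 difference of interferon-stimulated genes was -0.17, and -0.27 with no filter on low values. IFI44L fell 2.71-fold, IFI27 2.15-fold, IFI44 1.54-fold and IFI6 1.46-fold.

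Proteasome subunit genes fell in 7 of 27 tested members and rose in 0, also when adjusted over the list alone (median 1.09-fold lower, camera adjusted p = 0.00318, adjusted p = 0.554 with an estimated correlation). The 4 with the smallest p encode subunits of the regulatory cap. PSMD3 fell 1.42-fold, PSMD2 1.27-fold, PSMC4 1.26-fold and PSMD4 1.22-fold. On the log2 scale the list median was -0.13, and lay between -0.15 and -0.07 over all alternatives. The list's call was also lost with the mean of a gene's probe sets (adjusted p = 0.0867) and without probe sets ending in _x_at and _s_at (0.239), within a range of 1.63e-04 to 0.554 over all alternatives.

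Markers of fibroblasts and stellate cells were lower in 4 of 9 tested members and higher in 1, or 5 and 1 adjusted over the list alone (median 1.15-fold lower, camera adjusted p = 0.0134, adjusted p = 0.279 with an estimated correlation). The median log2 difference of the fibroblasts and stellate cells list was -0.20, and -0.40 without RNF43 siRNA replicate 3 or without both arrays numbered 3, and -0.54 with the upper 30% of probe sets. COL3A1, a fibrillar collagen, fell 2.54-fold, ACTA2, smooth muscle actin, 1.98-fold, FAP, a surface protease, 1.48-fold and the proteoglycan gene DCN 1.46-fold. The calls of the list and of DCN were lost without probe sets ending in _x_at and _s_at, at adjusted p = 0.185 for the list (2.47e-04 to 0.279 over all alternatives) and 0.633 for DCN (1.05e-04 to 0.633). Of the 9 members, 3 also stand in another list.

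**Figure D2:**
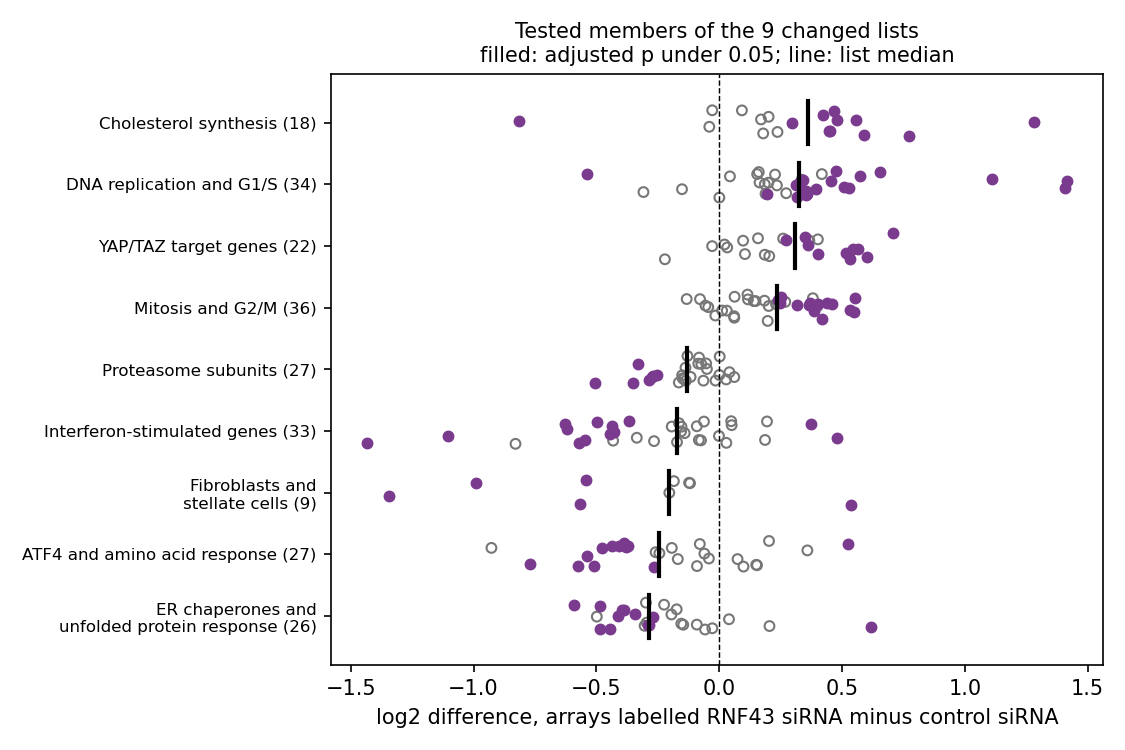
Log2 difference of each tested member (points) of the 9 changed gene lists, arrays labelled RNF43 siRNA minus control arrays, with the number of tested members in brackets; filled points passed adjusted p under 0.05 and the vertical line is the list median. The 4 lists with medians of 1.18-fold to 1.28-fold higher lie to the right of 0, and members of most lists lie on both sides.

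Neither Wnt list passed the camera test, although both passed as higher in fry (adjusted p = 0.0281 for Wnt/beta-catenin target genes and 0.0187 for Wnt receptors and signal transducers), and the target genes also passed in camera without control siRNA replicate 3 (adjusted p = 0.0392). Of 13 tested Wnt/beta-catenin target genes, 3 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.117, range over all alternatives 0.0281 to 0.554). These were CCND1, which encodes cyclin D1, at 1.90-fold (log2 difference 0.93, and 0.61 with the mean of its probe sets), the differentiation inhibitor ID2 at 1.67-fold and the Wnt antagonist DKK1 at 1.31-fold. ZNRF3, the paralogue of RNF43, had a log2 difference of 0.35 (SE 0.12) that did not pass (adjusted p = 0.0671), and passed with each array centred on its median (0.0412) and with the replicate block (0.0281). Of 29 tested Wnt receptors and signal transducers, 6 rose and 0 fell, again with the same counts adjusted over the list alone (camera adjusted p = 0.157, range over all alternatives 0.0187 to 0.698). LGR4, an R-spondin receptor, rose 2.50-fold (log2 difference 1.32, SE 0.08, limma adjusted p = 4.65e-06). The Frizzled receptor genes FZD6 and FZD1 rose 1.35-fold and 1.56-fold, and BTRC, a ubiquitin ligase subunit that targets beta-catenin, 1.61-fold. The FZD1 call was lost without control siRNA replicate 1 or any 1 array labelled RNF43 siRNA, without both arrays numbered 3 and with no filter on low values (adjusted p 0.0132 to 0.0878 over all alternatives). BTRC had a log2 difference of -0.03 without probe sets ending in _x_at and _s_at (adjusted p = 0.912, range over all alternatives 3.87e-04 to 0.912), and its call was also lost with the mean of its probe sets (0.462).

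Signals of cell type markers were also described on the control arrays. Genes of plasma proteins that hepatocytes secrete lay low, with a median percentile of 39.4 among all probe sets over 40 genes. Of 10000 random lists of 40 genes, read the same way, 0.54% had a lower median, and the median over these lists was 63.5. Only 7 of the 40 plasma protein genes reached the signal needed for testing. ALB, APOA1, TTR, FGB and SERPINA1, named after their values were seen, did not reach it, at mean log2 signals of 4.19, 5.18, 5.09, 3.94 and 4.65. RBP4 and C3, 2 of the 4 with the smallest p, did, at 10.61 and 12.78. Of the 7 tested plasma protein genes, 1 rose and 2 fell, or 2 and 2 adjusted over the list alone (adjusted p = 0.627). Cytosolic ribosomal protein genes had a median percentile of 99.8 over 46 genes, and 0 of them changed. The median was 62.3 for liver transcription factors, 70.7 for oncofetal liver genes and 87.8 for mesenchymal and invasion genes. In these lists 9 of 20, 6 of 17 and 3 of 26 genes lay below the median of all probe sets, so a list median does not speak for each member. Blood cell markers had a median percentile of 36.7, with 5 of 17 past the filter, and endothelial markers 37.1, with 4 of 14, too few to test. Markers of non-liver epithelial lines had a median of 35.5, and markers of fibroblasts and stellate cells a higher one of 56.3, with 9 of 16 past the filter. Probe sets differ in how strongly they bind, so these percentiles rank signals and not transcript abundances.

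**Figure D3:**
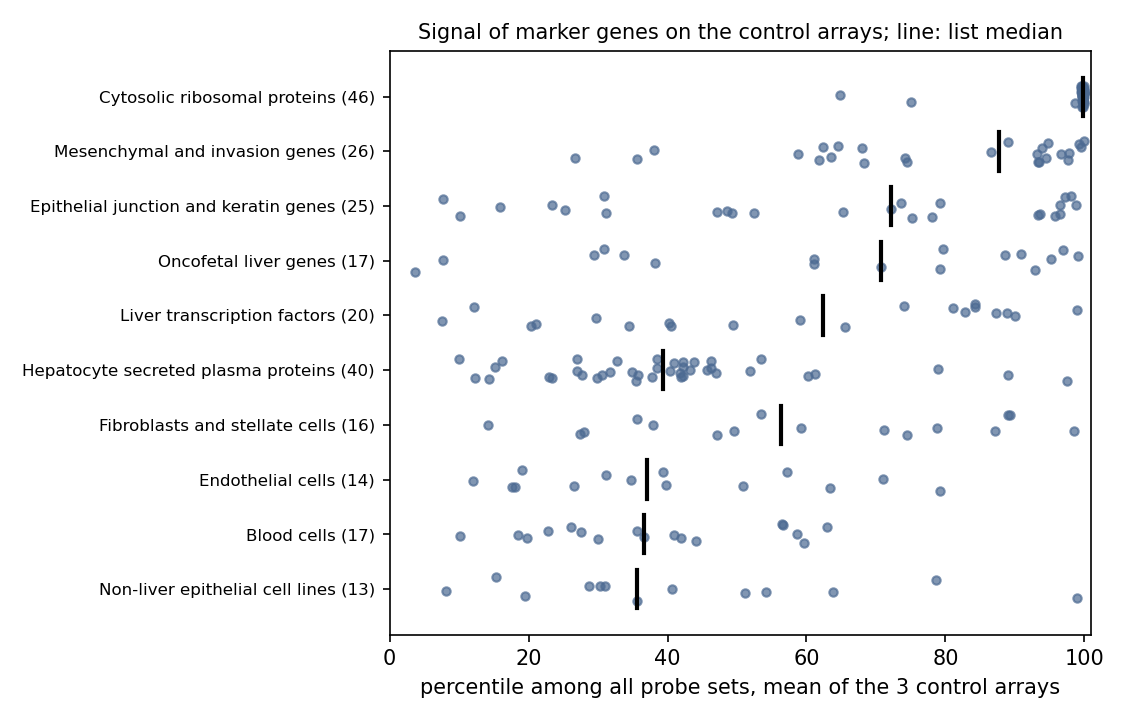
Percentile of each gene's brightest probe set among all probe sets (points), by the mean of the 3 control arrays, for 10 marker lists with the number of genes in brackets; vertical lines are list medians. Plasma protein genes centre on 39.4 and ribosomal protein genes on 99.8.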

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

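In this part, the limma fits, fits without 1 array, set tests and quantile normalization were planned, but their use as tests of an explanation, and the tests of marker levels and of other splits, were chosen after the result was seen, and only the test of neighbouring genes was chosen before. Probe sets outside the gene comparison also differed. Of 3526 tested probe sets that carry no gene name here, 156 were higher and 127 lower on the arrays labelled RNF43 siRNA (limma, adjusted p under 0.05, each probe set tested on its own). Where the groups did not overlap, the largest rise among them was 3.56-fold and the largest fall 3.26-fold. Of 1120 tested probe sets that name several genes, 58 were higher and 85 lower. In the same fit, 1944 of 22660 tested probe sets that name 1 gene were higher and 1849 lower. The share higher was 4.42% for unnamed probe sets and 5.18% for those naming several genes, below the 8.58% for those naming 1 gene.

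RNF43 was higher, not lower, on the arrays labelled RNF43 siRNA. An exchange of 1 array of each group is argued against, since the labelled split gave 2684 changed genes and every other of the 10 splits of the 6 arrays gave 0 in limma, with 79 to 751 genes at an unadjusted p under 0.05 against 4128. The RNF43 call did not rest on any 1 array, since the highest limma adjusted p over the fits without 1 array was 0.0342. It was lost at 0.0537 with both arrays numbered 3 left out. These fits reuse values of the main fit, so they cannot decide whether noise of a dim probe set made the difference. An exchange of all labels was not told apart from a true rise. Both allow the observed log2 difference of 0.64, and no other value examined here fixes the direction. Whether transcripts with matches to either siRNA moved was not tested. A rise of RNF43 as a Wnt/beta-catenin target may also stay open. The list of such targets had an adjusted p of 0.117 in camera and 0.0281 for a rise in fry. Without control siRNA replicate 3 its adjusted p in camera was 0.0392. Only 13 of 25 matched targets were bright enough to test, and 5 of these 13 also stand in another list. Whether the probe set reads a transcript that the siRNA does not cut was not tested.

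Plasma protein genes had low signals in cells labelled HepG2. Ribosomal protein genes kept a median percentile of 99.8, which argues only against a loss of signal so complete that abundant transcripts rank low. Percentiles are ranks, which scaling cannot move, so they cannot decide on failed scaling or weak labelling. An effect of the RNF43 siRNA is argued against by the levels in both groups. The plasma protein list had a median percentile of 39.4 on the control arrays and 39.6 on the arrays labelled RNF43 siRNA. It was thus low in both groups, whichever way the labels run. RNA of another line or culture than the label says stays open, since the median of 39.4 is the pattern itself. Liver transcription factors had a median percentile of 62.3, near the 63.5 of random lists, so this list median decides nothing. Those random lists held 40 genes, against 20 liver transcription factors. The 20 factors spread from a percentile of 7.47 to 98.9, with 9 below the median of all probe sets. Which of them bear on the identity of the line was not tested. RBP4 and C3 had high signals, but 33 of the 40 plasma protein genes lay below the median of all probe sets. Mesenchymal and invasion genes had a median percentile of 87.8. Arrays of other cell lines were not compared here. Weak probe sets for single genes were not tested as a cause.

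A large share of genes differed between groups of 3 arrays. Only 10 splits of the arrays exist, too few for a share under 0.05, and as many genes came from 1 split, the labelled one (2684, against at most 0 in the others). Array-wide intensity differences are argued against by quantile normalization, which gave 2695 genes, 2626 of them shared. Broad DNA copy number differences between cell populations are argued against by runs of 50 neighbouring genes, whose medians varied 1.06 times as much as after shuffling. A response to the RNF43 siRNA, an unintended target of either siRNA, and a difference between cultures or hybridisation days stay open and were not tested.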

How the results depend on the processing

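One alternative, both arrays numbered 3 left out, was chosen after the data were seen. The count of 2684 changed genes (1364 higher, 1320 lower) and its parts stayed within 1.5 times in 57 of 66 values under alternatives. Testing every probe set on its own gave 4219 (2158 higher, 2061 lower), since more features were tested, and requiring at least 2-fold gave 204 (114 and 90). Leaving out each array in turn gave 1741 to 2656 genes, 873 to 1409 higher and 868 to 1247 lower, and leaving out both arrays numbered 3 gave 2992 (1529 and 1463). RNF43 stayed higher under all 19 alternatives run for it, at 0.55 to 0.72 on the log2 scale without each array in turn, and lost its call with both arrays numbered 3 left out (0.48, adjusted p = 0.0537, range over alternatives 0.00585 to 0.0537), where the cause was not tested. The 9 changed lists became 0 with an estimated correlation and 17 with fry, which tests a different question, and stayed at 9 to 11 without each array in turn. With fry, 8 of the 9 passed in the same direction, and interferon-stimulated genes did not (adjusted p = 0.0578, range over alternatives 1.19e-04 to 0.554). Of 1554 values of named genes under alternatives, 1517 kept direction and side, 34 lost the call, 2 gained it and 1 reversed. The reversal was BTRC at -0.0293 without probe sets ending in _x_at and _s_at, where another probe set stood for the gene. Of 765 list values, 736 were kept, 13 lost and 16 gained a call. Centring each array on its median made 59.5% of changed genes higher, against 50.8%. The numbers were not taken as a pairing in the main fit, since the labels do not say that they pair cultures. Deviations of same-numbered arrays correlated at 0.16, 0.08 and 0.27, and those of other pairs across groups at -0.21 to 0.09. Variation shared by number may thus remain in the spread of the main fit. Control siRNA replicate 2 correlated best with RNF43 siRNA replicate 1 (0.09), and the other 5 arrays with their own number. The replicate block gave 3908 changed genes, kept the RNF43 call and 9 lists. The planned comparison of control probe sets for RNA quality and its alternatives were not run. Signal over background limits dim genes, and the calls of DNMT3L, PLA2G3 and POU2F2 were lost in some fits without 1 array, and that of CCDC106 in both such fits that tested it.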

Other observations

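The histone genes, and the lists described after them, were picked for description after their values were seen. Signals of many histone genes were lower on the arrays labelled RNF43 siRNA, and whether they follow total histone mRNA was not tested. Of 25 tested, 13 fell and 0 rose past the threshold, with a median of 1.59-fold lower (log2 -0.67, and -0.64 under both quantile normalization and median centring). None of the H3 genes passed, and H3C8 pointed the other way with a large error (log2 difference 2.18, SE 0.83, adjusted p = 0.0868), while the linker histone H1-3 had a log2 difference of -0.0074. H2BC12 fell from a log2 signal of 14.26 to 13.70, and H1-2, another linker histone, from 11.28 to 10.57. Many histone probe sets can bind several family members. Of 17 tested probe sets ending in _at alone, 14 lay below 0 and 7 fell, with a median log2 difference of -0.56. SLBP, which binds the 3' end of histone mRNA, rose 2.16-fold on the same arrays.

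Other groups held strong changes without passing as lists in camera. In fry, 3 of these 4 passed, NF-kappaB target genes as lower (adjusted p = 0.0128), epithelial junction and keratin genes as higher (0.0134) and NRF2 target genes as lower (0.041), and fatty acid and triglyceride synthesis did not (0.0578). In camera, NF-kappaB target genes passed with the mean of a gene's probe sets (adjusted p = 0.0231) and NRF2 target genes without RNF43 siRNA replicate 1 (0.0342). Among 20 tested NF-kappaB target genes, 6 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.157, range over alternatives 0.0128 to 0.554). The chemokine genes CXCL1, CXCL8 and CXCL2 fell 2.58-fold, 2.21-fold and 1.96-fold, and IL6 fell 1.51-fold. Among 17 epithelial junction and keratin genes, 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.286, range over alternatives 0.0134 to 0.895). KRT8 rose 1.65-fold, KRT18 1.33-fold and JUP 1.28-fold. KRT7 rose 1.61-fold, a call lost without probe sets ending in _x_at and _s_at (adjusted p = 0.168, range over alternatives 1.24e-06 to 0.168). Among 19 fatty acid and triglyceride synthesis genes, 5 rose and 3 fell, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.378, range over alternatives 0.0578 to 0.73). ACSL1, which activates fatty acids, rose 2.11-fold and the elongase ELOVL6 1.77-fold, while malic enzyme ME1 fell 1.59-fold (log2 difference -0.67, and -1.10 without probe sets ending in _x_at and _s_at). Among 23 NRF2 target genes, 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.135, range over alternatives 0.0342 to 0.56). AKR1B10, an aldo-keto reductase, fell 2.72-fold. For immediate early genes the median and mean log2 differences were 0.05 and 0.01 while the test pointed lower, and for genes of bile acid, drug and xenobiotic metabolism they were -0.03 and 0.08 while the test pointed higher (adjusted p = 0.964 for both). The lists that did not pass in camera had adjusted p from 0.101 to 0.964. The lowest was that of mesenchymal and invasion genes, which passed as lower in 3 alternatives, fry among them (adjusted p = 0.00937, range over alternatives 0.00315 to 0.439).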
